A study of Mus musculus with 22 samples.

How the data were processed

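RNA from 22 samples of RT2 mice was measured on Affymetrix Mouse Gene ST arrays, 1 array per sample. Per the labels, total RNA was purified with TRIzol and biotin-labelled by the whole-transcript sense target protocol. The series text says that tissues were dissected out or isolated, without saying which, and that the scanned images were processed with aroma.affymetrix. The version, background correction, normalization, summarization and chip definition are not given in the sources used here. The deposited values, normalized by the authors, are log2 intensities, a unit read from their range, and the 22 distributions nearly coincided, with medians from 7.08 to 7.22. No 2 arrays were identical, and the highest correlation between any 2 across genes was 0.9951. Arrays carry no read depth, and the number of arrays limits the precision.

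The deposited table held 35511 probe sets, of which 23410 were listed in the gene table used here. Of these, 21789 had 1 gene symbol and were kept, 1621 had several symbols and were left out, and 12101 probe sets were not listed. For the 999 genes with several probe sets the one with the highest mean over all arrays was used, which left 19938 genes and no filter on dim genes. A gene named as not analysed here had no probe set that met this rule. Genes are given by symbol, as the sources used here hold no coordinates for the probe sets.

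All 22 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group, so that the 6 groups shared 1 estimate of each gene's spread. The 7 comparisons were tested with limma's moderated test (two-sided), with Benjamini-Hochberg adjustment over the genes of each comparison and a call at an adjusted p below 0.05. Errors of fold changes are standard errors from this fit, and errors of levels are SDs. Gene groups were 26 lists, of which 25 had the minimum of 5 measured genes. The lists covered beta cells, other islet endocrine cells, neuroendocrine secretion, cell cycle, endothelium, pericytes and smooth muscle, fibroblasts and matrix, basement membrane, hypoxia, glycolysis, citrate cycle and respiration, and sterol and fatty acid synthesis. They also covered the unfolded protein response, pancreatic progenitors, imprinted and oncofetal genes, mesenchymal transition, neurons, macrophages, lymphocytes, neutrophils, acinar, ductal and hepatocyte cells, red blood cells, immediate-early and heat shock genes, and interferon. The red blood cell list had 3 measured genes of 9 and was not tested. Lists were tested against all other genes with camera at its preset correlation of 0.01, adjusted over all 175 tests, and again with a correlation estimated from the data. Member counts refer to the adjustment over all genes, and counts adjusted over the list alone are given where they differ. Figures were drawn with matplotlib 3.10.9.

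Named genes were the 8 largest rises and 8 largest falls among the called genes of each comparison, then up to 4 members with the smallest adjusted p of each list, of which those that the text needs are given. Predicted genes, open reading frames without a name, olfactory receptors and small RNAs were skipped, which passed over 2 genes among the rises from angiogenic islets to islet tumours. A further 8 genes were fixed for the overview (Ins1, Ins2, Mki67, Vegfa, Pecam1, Cpa1, Alb and Krt19). The groups, the comparisons, the tests, the gene lists and this rule were chosen before the data were examined. The Y-linked genes were chosen after Xist had been seen.

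The alternatives fixed at the same time were a block for the replicate code, a fit of only the compared arrays, quantile normalization, median centring, a filter that left 14953 genes, all probe sets, array weights, a trended and robust variance, a fold change of at least 1 log2, leaving out each array in turn, and fry. The acinar and the lymphocyte mean of each array as covariates were chosen after seeing the data. Whether replicate codes pair samples was checked by correlating, across genes, each array's deviation from its group mean. Normal and hyperplastic samples of the same code had correlations of 0.197 to 0.448, against -0.368 to -0.058 for other codes, and hyperplastic and angiogenic samples 0.353 to 0.479, against -0.393 to -0.062. Normal and angiogenic samples were less alike, with 0.057 to 0.144 against -0.09 to 0.039. Deviations within a group cancel, so positive values for the same code make the others lower. The block used 2006, 2007 or the prefix I, II or III of the title, so that the islets I-93 shared prefix I with tumours and metastases. Islets and tumours share no other code, and all metastases carry prefix I. With the block, comparisons of islets with tumours and of metastases with primaries are thus linked only through arrays of prefix I. The meaning of the codes is not given in the sources used here.

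The method was tested on simulated data with known changes. Noise was drawn independently for each gene and array, without correlation between genes, pairing by code or mixed tissue. The rates below may therefore not hold for the real arrays. With 3 against 3 arrays it recovered 46.7% of changes of 0.5 log2, 91.9% of changes of 1 and 100% of changes of 2, with 6 false calls among 169. With 5 against 5 arrays it recovered 65.2%, 96.8% and 100%, with 4 false calls among 179.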

Results

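Gene expression was measured on 22 Affymetrix Mouse Gene ST arrays, 1 array per sample, along the course of islet tumours in RIP1-Tag2 (RT2) mice. In this strain the insulin promoter drives a viral tumour antigen in pancreatic beta cells, and islets pass through overgrowth and vessel ingrowth to neuroendocrine tumours. The labels placed 3 samples each in normal, hyperplastic and angiogenic islets, 5 in islet tumours, 5 in metastasis-like primary tumours and 3 in liver metastases, named here by their titles. All 3 liver metastases share the title prefix I, while the primary tumours are spread over the prefixes I, II and III, whose meaning is not given in the sources used here. All 22 samples carry the RT2 genotype in their labels, the normal islets included. How primary tumours were assigned to the metastasis-like class is not given in the sources used here, so a choice made on expression itself cannot be excluded. The labels also do not say which samples came from separate animals, so each p-value measures the spread between samples. Medians of the deposited log2 values lay between 7.08 and 7.22 on every array, and the number of arrays limits the precision.

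On the first principal component of the gene levels, metastasis-like primaries and liver metastases stood apart from all other samples. That component held 48.9% of the variance. It ran from 43.87 to 49.84 in normal islets, from 25.21 to 33.61 in hyperplastic islets and from 16.53 to 27.23 in angiogenic islets. Islet tumours lay between 6.10 and 9.86, metastasis-like primaries between -42.52 and -30.39, and liver metastases between -53.49 and -48.05. Component 2 (13.5% of the variance) parted these last groups, with metastasis-like primaries between -14.72 and 1.62 and liver metastases between 20.27 and 27.53. Across genes, which are not independent replicates, metastasis-like primaries had a mean correlation of 0.964 with liver metastases and of 0.957 with islet tumours, and islet tumours had 0.937 with liver metastases. Single pairs of arrays overlapped, with 0.9515 to 0.9722 for metastasis-like primaries and metastases and 0.9501 to 0.9624 for metastasis-like primaries and islet tumours.

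**Figure D1:**
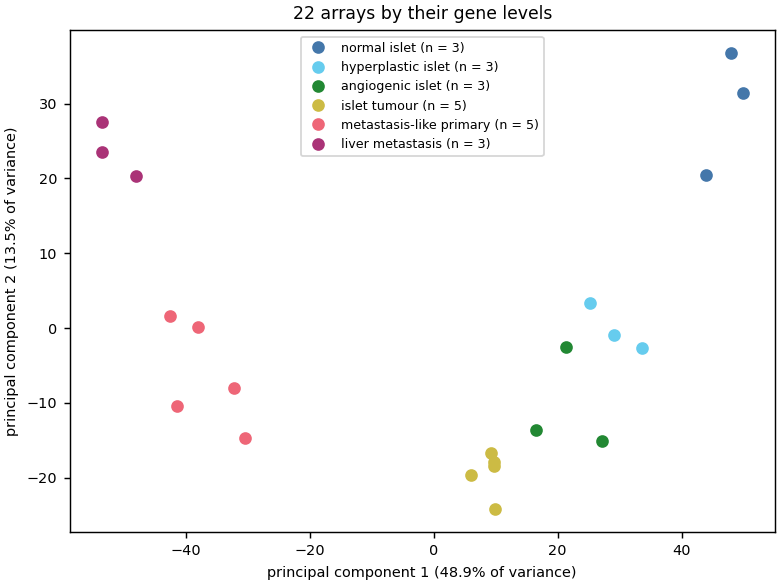
Principal components 1 and 2 of the log2 gene levels (unitless scores, with the percent of variance on each axis), 1 point per array, coloured by group. Metastasis-like primaries and liver metastases lie below -30 on component 1, and all other arrays lie above 6. On component 2 metastasis-like primaries lie between -14.72 and 1.62 and liver metastases between 20.27 and 27.53.

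Ins2, an insulin gene, stood at 10.99 ± 0.07 log2 in normal islets (SD, n = 3) and 11.01 ± 0.06 in islet tumours (n = 5), and at 10.17 ± 0.22 in metastasis-like primaries (n = 5) and 10.34 ± 0.17 in liver metastases (n = 3). Ins1, the other insulin gene, was not analysed here. The proliferation marker Mki67 averaged 7.49 ± 1.11 in normal islets, with single arrays from 6.52 to 8.70, and 10.13 ± 0.11 in hyperplastic islets. It averaged 10.61 ± 0.40 in islet tumours and 10.99 ± 0.15 in liver metastases. Vegfa, the main vessel growth factor, went from 10.62 ± 0.24 in islet tumours to 9.11 ± 0.20 in metastasis-like primaries. The endothelial marker Pecam1 was highest in angiogenic islets (9.83 ± 0.35) and averaged 7.90 ± 0.25 in metastasis-like primaries. Cpa1, a digestive enzyme of acinar cells, stood at 11.83 ± 1.88 in normal islets and 12.84 ± 0.11 in islet tumours, and at 11.24 ± 0.44 in liver metastases. The ductal keratin Krt19 averaged 7.98 in normal islets, 6.63 in islet tumours and 5.94 ± 0.14 in liver metastases. Albumin (Alb), a liver protein, averaged 7.06 ± 0.92 in islet tumours, 9.39 ± 1.61 in metastasis-like primaries and 13.04 ± 0.14 in liver metastases.

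**Figure D2:**
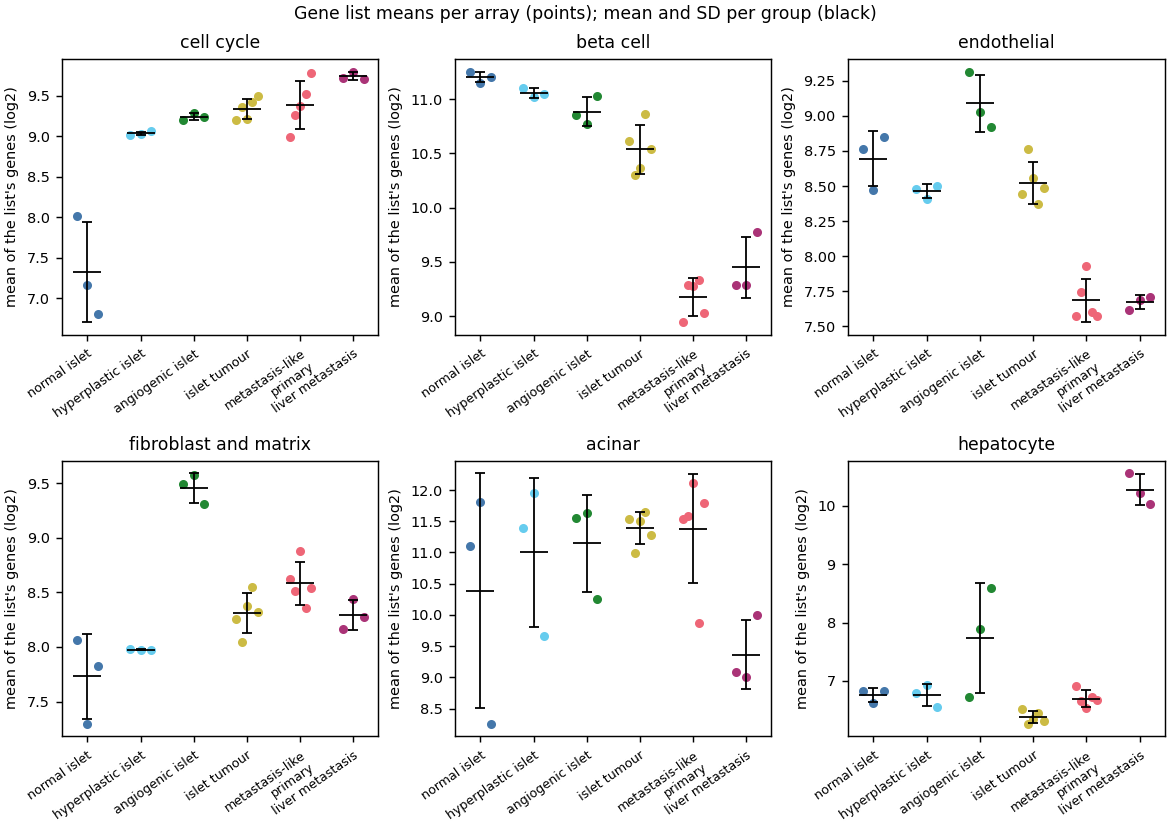
Mean log2 level of the genes of 6 lists on each array (points), by group, with the group mean and SD in black. Cell cycle genes averaged 7.33 in normal islets and 9.04 in hyperplastic islets, beta-cell genes 10.54 in islet tumours and 9.17 in metastasis-like primaries, and hepatocyte genes 10.28 in liver metastases.

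Cell cycle genes rose from normal to hyperplastic islets (3 against 3 arrays), the first step of islet overgrowth. Of 33 measured cell cycle genes, 32 were higher (33 adjusted over the list alone), by a median of 1.76 log2 (adjusted p = 1.88e-52, and adjusted p = 0.0382 with an estimated correlation). Neil3, a DNA repair glycosylase, rose 6.55-fold (2.71 ± 0.37 log2, SE, adjusted p = 3.22e-05). The mitotic checkpoint kinase Bub1 rose by 2.71 ± 0.35 log2, the topoisomerase Top2a by 2.67 ± 0.35 and Mki67 by 2.64 ± 0.36. The mitotic kinesins Kif11 (2.52) and Kif20b (2.41), the chromatin remodeller Hells (2.52) and Ect2 (2.37), which drives cytokinesis, followed. Other genes of the list rose as well, among them the helicase subunits Mcm6 (1.91 ± 0.20) and Mcm5 (1.81) and the kinase Cdk1 (2.12). The imprinted growth factor Igf2 rose by 2.19 ± 0.36 log2 (adjusted p = 0.000303) and the imprinted zinc finger gene Plagl1 by 1.14 ± 0.23. The neuronal RNA-binding gene Elavl3 rose by 0.86 ± 0.16 log2.

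Asb11 had the largest fall at this first step. It fell by 2.28 ± 0.14 log2 (adjusted p = 6.57e-09), and the cyclin D gene Ccnd2 fell by 1.69 ± 0.20 (adjusted p = 1.2e-05). The secreted phospholipase Pla2g2f (-2.02), the microvillus protein villin (Vil1, -1.95), Angptl7 (-1.82), the organic anion carrier Slco1a6 (-1.74), the glucuronosyltransferase Ugt2b34 (-1.66) and the sulfotransferase Sult1c2 (-1.65) fell too. Among regulators of pancreas development, Gata6 fell by 0.68 ± 0.11 and Neurog3 fell by 0.53 ± 0.11, while Sox4 rose by 0.78 ± 0.20. Their list had 1 gene higher and 3 lower of 15 and was not called (adjusted p = 0.535). Of 9 genes of the other islet endocrine cells, 2 fell, led by the delta-cell factor Hhex (-0.82 ± 0.18), with a list median of -0.46 (adjusted p = 0.00875, but adjusted p = 0.159 with an estimated correlation).

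Lymphocyte, macrophage and fibroblast genes were called higher in hyperplastic islets as lists, with few single genes past the test. Neutrophil, interferon, pericyte and basement membrane lists were not called (adjusted p = 0.106 to 0.729). Lymphocyte genes had a median of 0.66 log2 (adjusted p = 6.93e-05, but adjusted p = 0.654 with an estimated correlation), with 1 of 13 members past the test (8 adjusted over the list alone). Their mean on the arrays was 7.88 in HyperplasticI-93, 7.28 in Hyperplastic2006 and 6.70 in Hyperplastic2007, against 6.50 on average in normal islets. Macrophage genes had a median of 0.32 (2 of 14, adjusted p = 0.00729, but adjusted p = 0.744 with an estimated correlation). The macrophage call ended with the lymphocyte mean as a covariate (adjusted p = 0.26). Fibroblast and matrix genes had a median of 0.20 (1 of 17, adjusted p = 0.0296, but adjusted p = 0.756 with an estimated correlation). That call rested on Normal2006 (0.836 without it), and it ended with array weights (0.461), without dim genes (0.0528) and with the lymphocyte covariate (0.149).

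In all, 1722 of 19938 genes differed between hyperplastic and normal islets, 890 higher and 832 lower. With each array centred on its median the share that was higher went from 51.7% to 37.9%, so the majority turned. Normal and hyperplastic samples of the same replicate code resembled each other, and with the code as a block 2112 genes were called. The block also called the endothelial list lower (median -0.23, adjusted p = 0.0115, against 0.0539 without it) and the acinar list higher (median 0.58, 0.0215 against 0.133). With the lymphocyte mean as a covariate the count was 1118. Of 25 lists, 5 were called, 4 of them higher, and 8 without Hyperplastic2006.

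From hyperplastic to angiogenic islets (3 against 3 arrays), the step at which vessels grow in, connective tissue and vessel genes rose together. Of 17 fibroblast and matrix genes, 16 rose (17 adjusted over the list alone), by a median of 1.43 log2 (adjusted p = 1.26e-43, and adjusted p = 0.00344 with an estimated correlation). Fibronectin (Fn1) rose 4.83-fold (2.27 ± 0.22 log2, SE, adjusted p = 1.07e-05) and Thbs4, a matrix thrombospondin, rose 5.34-fold (2.42 ± 0.32, adjusted p = 0.000134). The fibrillar collagens Col1a2 (2.12), Col1a1 (2.02) and Col3a1 (1.91), the proteoglycans Lum (2.09) and Bgn (1.93) and periostin (Postn, 1.85) rose with them. Endothelial genes had a median rise of 0.62, with 6 of 13 past the test (11 adjusted over the list alone, adjusted p = 2.94e-16, and adjusted p = 0.0359 with an estimated correlation). The endothelial cadherin Cdh5 rose by 1.00 ± 0.13, Pecam1 by 0.96 ± 0.18 and the clotting factor Vwf by 0.95 ± 0.19.

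Basement membrane genes rose in 8 of 9 cases, by a median of 0.84 (adjusted p = 7.13e-21, and adjusted p = 0.00344 with an estimated correlation), among them the collagens Col4a1 (0.96 ± 0.11) and Col4a2 (0.98) and the laminin chain Lamb1 (0.84). Pericyte and smooth muscle genes rose in 6 of 10 cases (9 adjusted over the list alone), by a median of 0.92 (adjusted p = 7.08e-17, and adjusted p = 0.0272 with an estimated correlation). Their members Pdgfrb, the receptor that recruits pericytes (1.04 ± 0.14), Rgs5 (0.99) and Tagln (1.22) rose. Genes of the mesenchymal transition list rose in 4 of 13 cases (6 adjusted over the list alone, adjusted p = 2.14e-07, and adjusted p = 0.00863 with an estimated correlation), led by the fibronectin receptor chain Itga5 (0.86 ± 0.11), vimentin (Vim, 1.15) and Zeb2 (0.96).

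Macrophage genes rose in 8 of 14 cases (14 adjusted over the list alone), by a median of 0.74 (adjusted p = 9.84e-18, but adjusted p = 0.0552 with an estimated correlation), among them the endotoxin receptor Cd14 (0.56 ± 0.11). Hepatocyte genes had a median of 0.81, with 2 of 18 past the test (14 adjusted over the list alone, adjusted p = 1.67e-12, but adjusted p = 0.184 with an estimated correlation). Their mean was 7.90 in Angiogenic2006 and 8.59 in Angiogenic2007 but 6.72 in AngiogenicI-93, and Alb stood at 11.30, 11.81 and 8.02 in the same samples. Cell cycle genes had a median of 0.21 and interferon genes of 0.35, each with 0 members past the test (adjusted p = 0.00058 and 0.00506, but adjusted p = 0.804 and 0.753 with an estimated correlation). Immediate-early and heat shock genes had a median of -0.33 (adjusted p = 0.00875, but adjusted p = 0.654 with an estimated correlation). That last call ended without HyperplasticI-93 (0.0638), Hyperplastic2007 (0.0773) or Angiogenic2006 (0.0957).

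Fewer genes fell than rose at this step. Defb1, an epithelial defensin, fell by 1.14 ± 0.22 log2 (adjusted p = 0.00482). The Wnt antagonist Sfrp5 (-0.72), the incretin receptor gene Gipr (-0.56), Ugt2b34 (-0.75), the early response gene Fosb (-0.72), Rasd1 (-0.68), Ppp1r17 (-0.66) and Ccdc162 (-0.59) had adjusted p from 0.0123 to 0.039. Each of these 7 calls ended without HyperplasticI-93 (0.0506 to 0.132) and without Angiogenic2006 (0.0864 to 0.245). Some ended without Hyperplastic2006 (5 calls, 0.0639 to 0.138), Hyperplastic2007 (4 calls, 0.0545 to 0.246), AngiogenicI-93 (3 calls, 0.0743 to 0.117) or Angiogenic2007 (Sfrp5, 0.0533). A fit of the 6 arrays alone ended those of Ugt2b34 (0.0937), Fosb (0.157) and Ccdc162 (0.0533), and quantile normalization that of Ppp1r17 (0.0875).

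In all, 505 genes differed between angiogenic and hyperplastic islets, 456 higher and 49 lower, and 616 with the replicate code as a block. With median centring 373 were higher and 114 lower, so the share that was higher went from 90.3% to 76.6%. The count was 275 without Hyperplastic2006, 316 without Hyperplastic2007, 284 without Angiogenic2006 and 869 without Angiogenic2007. Array weights gave 930, of which 197 were lower. With the block, lymphocyte genes (median 0.25) passed as a list (adjusted p = 0.0164, against 0.0595 without it). Without the block 0 of 13 members passed the test, and the list had adjusted p = 0.831 with an estimated correlation. The pairs of the same code disagreed. The list mean rose from HyperplasticI-93 (7.88) to AngiogenicI-93 (8.42) and from Hyperplastic2006 (7.28) to Angiogenic2006 (7.89). It fell from Hyperplastic2007 (6.70) to Angiogenic2007 (6.32). Of 25 lists, 10 were called, 9 of them higher, and 5 held with an estimated correlation.

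Between angiogenic islets and islet tumours (3 and 5 arrays), hormones of the other islet endocrine cells and early response genes fell. Somatostatin (Sst) fell by 3.71 ± 0.22 log2 (SE, adjusted p = 5.01e-10), and peptide YY (Pyy, -3.75 ± 0.24) and glucagon (Gcg, -2.93 ± 0.45) fell with it. Of 9 genes of these cells 6 fell, by a list median of -0.78 (adjusted p = 6.8e-09, and adjusted p = 0.00344 with an estimated correlation). Immediate-early and heat shock genes fell in 12 of 13 cases (13 adjusted over the list alone), by a median of -1.79 (adjusted p = 8.02e-33, and adjusted p = 0.00344 with an estimated correlation). Fos (-3.48 ± 0.20), Fosb (-2.97 ± 0.17), Jun (-2.44 ± 0.16) and the chaperone gene Hspa1a (-2.94 ± 0.20) fell. On the arrays the list averaged 9.18 to 9.75 in all 9 islet samples and 7.31 to 8.15 in all 13 tumour and metastasis samples.

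Xist, the RNA that silences 1 X chromosome in female cells, had the largest fall (-4.92 ± 0.18 log2, adjusted p = 3.5e-13). It stood between 10.67 and 11.41 in all 9 islet samples and between 5.33 and 6.46 in the 13 tumour and metastasis samples. The Y-linked genes Kdm5d, Eif2s3y and Uty averaged 7.48 ± 0.95 (SD) in the islet samples and 8.80 ± 0.50 in the others.

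**Figure D3:**
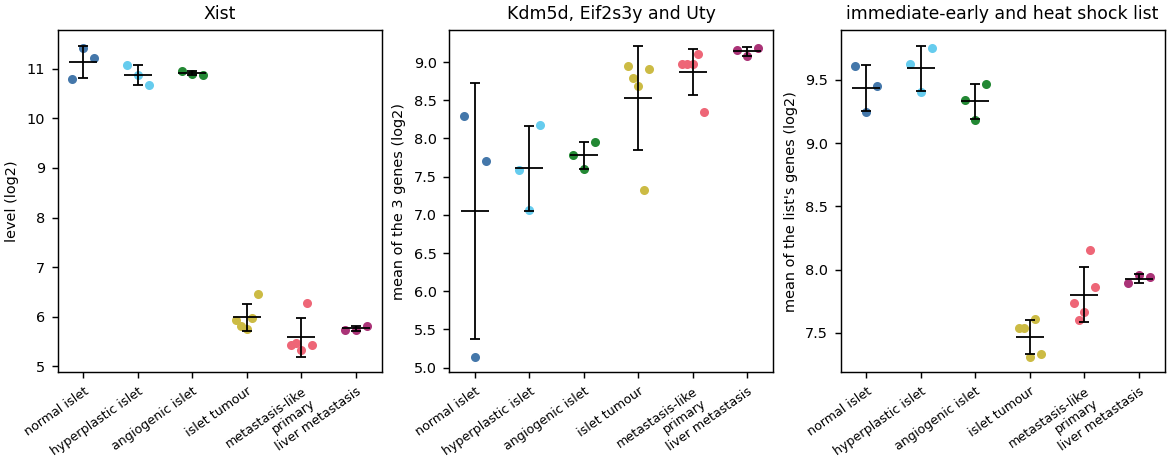
Log2 level of Xist, mean log2 level of the Y-linked genes Kdm5d, Eif2s3y and Uty, and mean log2 level of the immediate-early and heat shock list on each array (points) by group, with the group mean and SD in black. Xist lies above 10.6 in all 9 islet arrays and below 6.5 in the 13 others, and the early genes lie above 9.1 and below 8.2.

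Connective tissue and vessel genes fell between angiogenic islets and islet tumours. Fibroblast and matrix genes fell in 16 of 17 cases (17 adjusted over the list alone), by a median of -0.96 (adjusted p = 2.9e-22, and adjusted p = 0.0272 with an estimated correlation), among them the proteoglycans Dcn (-2.14 ± 0.28) and Lum (-2.06) and the collagen Col6a1 (-1.18). Basement membrane genes fell in 8 of 9 cases (median -0.58, adjusted p = 9.29e-09, but adjusted p = 0.059 with an estimated correlation), among them Col4a1 (-0.72 ± 0.10) and the perlecan gene Hspg2 (-0.58). Endothelial genes fell in 9 of 13 cases (12 adjusted over the list alone, median -0.58, adjusted p = 1.1e-10, but adjusted p = 0.107 with an estimated correlation), among them Pecam1 (-0.99 ± 0.16), whose call ended with the lymphocyte covariate (0.105). Pericyte genes fell in 7 of 10 cases (9 adjusted over the list alone, median -0.71, adjusted p = 3.04e-08, but adjusted p = 0.153 with an estimated correlation), among them the muscle filament gene Des (-1.22 ± 0.22). Mesenchymal transition genes fell in 3 of 13 cases (5 adjusted over the list alone, median -0.13, adjusted p = 0.00968, but adjusted p = 0.184 with an estimated correlation).

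Hepatocyte genes fell in 13 of 18 cases (18 adjusted over the list alone), by a median of -1.19 (adjusted p = 1.92e-15, but adjusted p = 0.126 with an estimated correlation), among them the fatty acid binding gene Fabp1 (-2.63 ± 0.27). Fabp1 did not follow the list mean: it stood at 7.06 in AngiogenicI-93 (list mean 6.72) and 6.81 in Angiogenic2006 (7.90). It also averaged 6.20 in normal islets, above islet tumours (4.66). The fall of Alb (-3.32 ± 0.82, adjusted p = 0.0133), whose values overlapped between the groups, was lost without Angiogenic2006 (0.0815) or Angiogenic2007 (0.079), the angiogenic samples with the highest hepatocyte means. Lymphocyte genes fell in 9 of 13 cases (12 adjusted over the list alone, median -1.09, adjusted p = 1.3e-09, but adjusted p = 0.339 with an estimated correlation). Their mean was 8.42 in AngiogenicI-93 and 7.89 in Angiogenic2006 but 6.32 in Angiogenic2007, which lay within the range of islet tumours (6.20 to 6.51). Interferon genes had a median of -0.40, with 1 of 13 past the test (adjusted p = 0.000767, but adjusted p = 0.701 with an estimated correlation and 0.226 with the lymphocyte covariate).

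The beta-cell glucose transporter gene Slc2a2 fell by 2.06 ± 0.33 log2 (adjusted p = 0.000489). Beta-cell genes as a group had a median of -0.24, with 1 of 19 past the test (3 adjusted over the list alone, adjusted p = 0.00267, but adjusted p = 0.64 with an estimated correlation), and the call ended without Angiogenic2007 (0.0774). Unfolded protein response genes fell in 6 of 13 cases and rose in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.000255, but adjusted p = 0.339 with an estimated correlation). The lipid desaturase Scd1 fell by 1.99 ± 0.28, in a sterol and fatty acid list with 3 of 15 members lower (6 lower and 2 higher adjusted over the list alone, adjusted p = 0.0178, but adjusted p = 0.594 with an estimated correlation). That list's call ended with quantile normalization (0.0545), without dim genes (0.0544) and with the lymphocyte covariate (0.105). Rises were smaller. The antisense RNA Phtf1os (1.26 ± 0.14), the neuronal cell surface gene Clstn2 (1.07 ± 0.14), the sodium-gated potassium channel gene Kcnt1 (1.07 ± 0.12) and Elavl3 (0.98 ± 0.14) rose. Edil3 (1.22), Nxph1 (1.20) and the calcium channel gene Cacna1e (1.14) rose too, but not with the lymphocyte covariate (0.198, 0.0614 and 0.11).

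The rises of the amino acid carrier Slc6a15 (1.52 ± 0.45, adjusted p = 0.0384) and the vesicular glutamate carrier Slc17a6 (1.12 ± 0.28, adjusted p = 0.0153) lost their calls when any 1 of several samples was left out. Without AngiogenicI-93 their adjusted p were 0.139 and 0.0852, and without Angiogenic2006 0.0974 and 0.054. The call of Slc6a15 also ended without Angiogenic2007 (0.0881), islet tumour I-9811 (0.0877) or III-8017 (0.0717). Both ended in a fit of the 8 arrays alone (0.0668 and 0.0627) and with the lymphocyte covariate (0.407 and 0.257), and that of Slc6a15 with a trended robust variance (0.0623).

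In all, 1903 genes differed between islet tumours and angiogenic islets, 617 higher and 1286 lower. With median centring the share that was higher went from 32.4% to 51.7%, so the majority turned. The count was 732 without AngiogenicI-93, 1025 without Angiogenic2006, 768 in a fit of the 8 arrays alone and 321 with the lymphocyte covariate. Of 25 lists, 13 were called, all lower, and 3 held with an estimated correlation. As Xist and the early response genes parted all islet from all tumour samples, sex makeup and handling cannot be told apart from tumour stage in these counts.

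Metastasis-like primaries differed from islet tumours (5 against 5 arrays) by the loss of mature beta-cell genes. Of 19 beta-cell genes, 14 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -1.16 log2 (adjusted p = 1.83e-11, but adjusted p = 0.0715 with an estimated correlation). The membrane protease Bace2 was 10.7-fold lower (-3.42 ± 0.16 log2, SE, adjusted p = 1.78e-12). The beta-cell peptide urocortin (Ucn3) fell by 3.28 ± 0.22, and the glucose-6-phosphatase gene G6pc2 (-3.22 ± 0.26) and the incretin receptor Glp1r (-3.11 ± 0.23) fell too. The fatty acid receptor Ffar1 was 7.98-fold lower. Pdx1, the transcription factor that maintains beta cells, fell by 2.76 ± 0.14 (adjusted p = 3.05e-12). The calcium pump gene Atp2a3 (-2.93), the lipid kinase Pip5k1b (-2.80) and the fatty acid oxidation gene Hadh (-2.79) fell with them. Insm1, a neuroendocrine transcription factor, fell by 1.73 ± 0.15 and the granule protein Scg3 fell by 1.79 ± 0.18, while the granule gene Ptprn rose by 0.87 ± 0.13.

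The largest rises in metastasis-like primaries were of other kinds. Serpina1c, an antitrypsin of the liver, rose 15.4-fold (3.95 ± 0.60 log2, adjusted p = 3.22e-05). The developmental transcription factors Tfap2b (3.49 ± 0.26) and Pou3f4 (3.34 ± 0.18), the imprinted gene Peg10 (3.40 ± 0.35), the GABA receptor subunit Gabrb1 (3.35 ± 0.16), the X-linked gene Nexmif (3.35 ± 0.13), the glutathione peroxidase Gpx3 (3.27 ± 0.28) and the neuropeptide Cartpt (3.13 ± 0.45) rose too. The alpha-cell factors Irx1 (1.86) and Irx2 (1.85) and transthyretin (Ttr, 1.57) rose, while Pyy fell (-0.98). For the list of other islet endocrine genes these gave 3 higher and 4 lower (3 and 5 adjusted over the list alone), a median of -0.38, a mean of 0.05 and a test directed upward (adjusted p = 0.531), so median and test differed in sign. Lin28b, an RNA-binding factor of fetal tissue, rose by 2.37 ± 0.21, while Igf2 fell by 2.74 ± 0.28 and Plagl1 fell by 1.20 ± 0.18. The imprinted and oncofetal list as a whole did not pass the test (3 higher and 2 lower of 13, median -0.10, mean 0.17, directed upward, adjusted p = 0.84).

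Vessel genes were lower in metastasis-like primaries. Endothelial genes fell in 11 of 13 cases, by a median of -0.85 (adjusted p = 6.8e-09, but adjusted p = 0.153 with an estimated correlation), among them the fenestration gene Plvap (-1.56 ± 0.15) and the growth factor receptors Kdr (-1.46) and Flt1 (-1.14). Their ligand gene Vegfa was 2.84-fold lower (adjusted p = 4.78e-10). Pericyte genes fell in 5 of 10 cases (7 adjusted over the list alone, median -0.45, adjusted p = 0.00294, but adjusted p = 0.64 with an estimated correlation). Basement membrane genes fell in 6 of 9 cases (7 adjusted over the list alone, median -0.46, adjusted p = 0.00319, but adjusted p = 0.468 with an estimated correlation), among them Hspg2 (-0.63 ± 0.08). Ductal genes went both ways (2 higher and 4 lower of 11, 3 and 4 adjusted over the list alone, adjusted p = 0.634), and the keratin Krt7 fell by 2.34 ± 0.15.

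Glycolysis genes rose in 8 of 15 cases and fell in 1 (9 and 1 adjusted over the list alone), by a median of 0.52 (adjusted p = 0.00541, but adjusted p = 0.594 with an estimated correlation), among them Pfkp (0.89 ± 0.12), Tpi1 (0.73 ± 0.10) and pyruvate kinase (Pkm, 0.59 ± 0.08). Pyruvate carboxylase (Pcx), which feeds the citrate cycle, fell by 1.75 ± 0.09 (adjusted p = 2.99e-12). Hypoxia genes did not pass as a list (5 higher and 2 lower of 15, adjusted p = 0.327). Immediate-early and heat shock genes rose in 4 of 13 cases (5 adjusted over the list alone, median 0.27, adjusted p = 0.0172, but adjusted p = 0.701 with an estimated correlation), among them Jun (0.87 ± 0.14). Neuronal genes rose in 5 of 10 cases and fell in 1 (6 and 1 adjusted over the list alone, median 0.53, adjusted p = 0.0431, but adjusted p = 0.645 with an estimated correlation), led by Elavl3 (1.38 ± 0.12) and the synaptic vesicle gene Syt1 (2.10 ± 0.25). The neuronal call ended without islet tumour II-649 (0.07) or II-6415 (0.0566), without metastasis-like primary III-8016 (0.0774) or III-8023 (0.0544), in a fit of the 10 arrays alone (0.0608) and without dim genes (0.0737).

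Some liver genes were higher in metastasis-like primaries without the others. Transferrin (Trf) rose by 1.91 ± 0.23 log2 and Apoc3 by 1.39 ± 0.22, while Tat fell by 1.77 ± 0.18. Alb rose by 2.33 ± 0.71 (adjusted p = 0.0172) with overlapping values, and its call ended without metastasis-like primary III-8016 (0.0595). In all, 5279 genes differed between metastasis-like primaries and islet tumours, 2455 higher and 2824 lower. Of 25 lists, 7 were called, 3 of them higher, and 0 held with an estimated correlation.

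Liver metastases differed from metastasis-like primaries (5 arrays) first by liver transcripts: all 18 of 18 hepatocyte genes were higher in the 3 metastases, by a median of 3.55 log2 (adjusted p = 5.37e-38, and adjusted p = 0.0106 with an estimated correlation). The drug-metabolising cytochrome Cyp2e1 was 37.7-fold higher (5.24 ± 0.42 log2, SE, adjusted p = 1.16e-08) and hemopexin (Hpx), a plasma heme carrier, rose by 5.17 ± 0.26. The carboxylesterase Ces1c (5.15), the cytochrome Cyp3a11 (5.14), the fibrinogen chains Fgg (4.77) and Fgb (4.75), the protease inhibitor Pzp (4.58) and fetuin (Ahsg, 4.56) rose as well. Among metabolic genes, citrate cycle and respiration genes rose in 6 of 19 cases (8 adjusted over the list alone, median 0.19, adjusted p = 1e-04, but adjusted p = 0.382 with an estimated correlation), among them fumarate hydratase (Fh1, 0.35 ± 0.08). The lipid desaturase Scd1 rose by 1.51 ± 0.28. No hepatocyte mean was used as a covariate, so how far liver tissue in the metastases adds to these rises, or to the falls given below, was not tested.

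Exocrine transcripts were lower in the metastases than in metastasis-like primaries. Acinar genes fell in 12 of 19 cases (18 adjusted over the list alone), by a median of -2.03 (adjusted p = 2.66e-07, but adjusted p = 0.654 with an estimated correlation). The secreted lectins Reg3g (-3.69 ± 0.62), Reg3b (-3.61 ± 0.54) and Reg3a (-2.94 ± 0.61), the elastase Cela3b (-3.03 ± 0.72), the trypsin inhibitor Spink1 (-2.98 ± 0.62) and the granule protein Zg16 (-2.98 ± 0.83) had the largest falls of this kind. Zg16 lost its call without liver metastasis I-9820 (0.0763) or I-9821 (0.0821). With the acinar mean as a covariate the calls of Spink1 (0.0674) and Reg3a (0.0778), which are not in that list, ended. The acinar mean was 9.88 in metastasis-like primary III-8016 and 11.54 to 12.12 in the other 4, against 9.01 to 9.99 in the metastases.

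Genes outside the exocrine list fell in the metastases too. The neuronal membrane glycoprotein Gpm6a fell by 3.89 ± 0.45 log2 (adjusted p = 2.34e-06), and the neuropeptide galanin (Gal, -2.88 ± 0.32), Lin28b (-2.72 ± 0.24) and the neuronal RNA-binding gene Elavl4 (-1.24 ± 0.11) fell with it. Macrophage genes fell in 9 of 14 cases (11 lower and 1 higher adjusted over the list alone, median -0.66, adjusted p = 1.21e-05, but adjusted p = 0.468 with an estimated correlation), among them the complement gene C1qa (-1.04 ± 0.17) and lysozyme (Lyz2, -1.42 ± 0.25). Cell cycle genes rose in 4 of 33 cases, by a median of 0.39 (adjusted p = 2.52e-05, but adjusted p = 0.753 with an estimated correlation), among them the cyclin Ccne1 (0.52 ± 0.13) and the mitotic activator Cdc20 (0.63 ± 0.16). Fibroblast and matrix genes fell in 3 of 17 cases (4 adjusted over the list alone, adjusted p = 0.0107, but adjusted p = 0.744 with an estimated correlation), among them Timp1 (-0.94 ± 0.18), a call that ended without metastasis-like primary II-6413 (0.0543). Interferon genes fell in 2 of 13 cases (4 adjusted over the list alone, median -0.51, adjusted p = 0.00288, but adjusted p = 0.744 with an estimated correlation and 0.0687 with the acinar covariate).

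In all, 3126 genes differed between liver metastases and metastasis-like primaries, 1556 higher and 1570 lower. With median centring the share that was higher went from 49.8% to 58.9%, so the majority turned. The count was 1950 without liver metastasis I-9821, 1988 without I-9822, 1910 with the acinar covariate and 5377 with array weights. Of 25 lists, 7 were called, 3 of them higher, and 1 held with an estimated correlation.

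Liver metastases differed from islet tumours (3 against 5 arrays) by the liver genes, the loss of beta-cell genes and the fall of vessel genes together. Alb was 63.3-fold higher (5.98 ± 0.82 log2, SE, adjusted p = 6.44e-06), and 18 of 18 hepatocyte genes rose (median 4.08, adjusted p = 4.86e-22, but adjusted p = 0.0552 with an estimated correlation). Cyp3a11 (5.24), Cyp2e1 (5.18), Ces1c (5.15), Ahsg (5.09), Hpx (5.04) and Serpina1c (adjusted p = 8.09e-06) were among the largest rises. The calcitonin receptor gene Calcr, outside that list, was 42.0-fold higher (5.39 ± 1.01, adjusted p = 0.00024). Beta-cell genes fell in 13 of 19 cases and rose in 1 (median -0.86, adjusted p = 1.56e-06, but adjusted p = 0.254 with an estimated correlation), among them Ucn3 (-2.95), Glp1r (-2.66), Pdx1 (-2.27 ± 0.16) and Nkx6-1 (-2.02). Bace2 fell by 3.08 ± 0.18 (adjusted p = 7.16e-11), and Ffar1 (-2.98), the sodium channel gene Scn9a (-2.93) and Atp2a3 (-2.92) fell with it.

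Endothelial genes fell in 10 of 13 cases (median -0.83, adjusted p = 6.18e-06, but adjusted p = 0.339 with an estimated correlation), with Plvap at -2.22 ± 0.18 and Kdr at -1.27, and Vegfa fell by 1.51 ± 0.12. Glycolysis genes rose in 7 of 15 cases and fell in 2 (median 0.37, adjusted p = 0.0165, but adjusted p = 0.654 with an estimated correlation), among them Tpi1 (1.11 ± 0.12), Pgk1 (1.13) and the lactate carrier Slc16a3 (1.32). Citrate cycle and respiration genes rose in 11 of 19 cases and fell in 1 (12 and 1 adjusted over the list alone, median 0.27, adjusted p = 0.000471, but adjusted p = 0.468 with an estimated correlation), with Mdh1 up by 0.74 and Pcx down (-1.58). Cell cycle genes rose in 14 of 33 cases and fell in 1 (15 and 1 adjusted over the list alone, median 0.44, adjusted p = 0.00053, but adjusted p = 0.804 with an estimated correlation), among them Ccne2 (0.89) and the chromatin silencer Ezh2 (0.73). Macrophage genes fell in 10 of 14 cases and rose in 2 (median -0.75, adjusted p = 0.00319, but adjusted p = 0.701 with an estimated correlation), with C1qa at -1.50 and Lyz2 at -1.60.

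Acinar genes fell in 17 of 19 cases (18 adjusted over the list alone, median -2.10, adjusted p = 0.000342, but adjusted p = 0.753 with an estimated correlation), among them Cela3b (-3.10 ± 0.72), Zg16 (-2.98 ± 0.83) and the granule gene Sycn (-2.89 ± 0.84). Immediate-early and heat shock genes rose in 6 of 13 cases and fell in 1 (7 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.0172, but adjusted p = 0.701 with an estimated correlation and 0.164 with the acinar covariate). Basement membrane genes fell in 6 of 9 cases and rose in 1 (median -0.42, adjusted p = 0.0491, but adjusted p = 0.701 with an estimated correlation). That last call ended without any 1 of islet tumours II-649 (0.0613), II-6415 (0.075), III-8017 (0.0596) and III-8024 (0.0556) or liver metastases I-9821 (0.055) and I-9822 (0.0558). It also ended without dim genes (0.0871) and with the lymphocyte covariate (0.0539). Pancreatic progenitor genes moved both ways (5 higher and 5 lower of 15, adjusted p = 0.864), and 1 of 10 neutrophil genes was higher (0 adjusted over the list alone, adjusted p = 0.791). In all, 7296 genes differed, 3451 higher and 3845 lower. With median centring the share that was higher went from 47.3% to 52.1%, so the majority turned. Of 25 lists, 10 were called, 5 of them higher, and 0 held with an estimated correlation. How far liver tissue in the metastases adds to the changes outside the hepatocyte list was not tested here either.

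Islet tumours set against normal islets (5 against 3 arrays) spanned the course from islet to tumour. All islet samples also differed from all tumour samples in Xist and in immediate-early and heat shock genes. Sex makeup and handling therefore cannot be told apart from tumour stage in this comparison. All 33 of 33 cell cycle genes rose, by a median of 2.01 log2 (adjusted p = 7.08e-34, but adjusted p = 0.115 with an estimated correlation). Bub1 was 9.57-fold higher (3.26 ± 0.32 log2, SE, adjusted p = 8.5e-08), and Neil3 (3.21), Kif11 (3.18), Top2a (3.16), Mki67 (3.12 ± 0.32) and Hells (3.12) rose too. Igf2 rose by 2.60 ± 0.32, Plagl1 by 2.02 ± 0.20 and Elavl3 by 2.07 ± 0.14. The hormone somatostatin (Sst) fell by 4.98 ± 0.22 (adjusted p = 1.59e-12) and Pyy fell by 4.66 ± 0.24, and 8 of 9 genes of the other endocrine cells fell (median -1.29, adjusted p = 1.49e-08, and adjusted p = 0.00344 with an estimated correlation). Beta-cell genes fell in 8 of 19 cases (9 adjusted over the list alone, median -0.49, adjusted p = 0.00202, but adjusted p = 0.637 with an estimated correlation), led by Slc2a2 (-3.04 ± 0.33) and Nkx6-1 (-1.21). Xist (-5.16 ± 0.18), Ccnd2 (-3.90 ± 0.18), Ugt2b34 (-4.69), the tetraspanin Tspan8 (-4.19), Vil1 (-3.84) and the sulfotransferase Sult1d1 (-3.75) fell.

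Macrophage genes rose in 10 of 14 cases from normal islets to islet tumours (median 1.05, adjusted p = 4.16e-07, but adjusted p = 0.367 with an estimated correlation), among them the lysosomal marker Cd68 (1.75 ± 0.17) and Lyz2 (1.91). Fibroblast and matrix genes rose in 10 of 17 cases (11 higher and 1 lower adjusted over the list alone, median 0.71, adjusted p = 0.000473, but adjusted p = 0.64 with an estimated correlation), led by Fn1 (2.24 ± 0.19). Basement membrane genes rose in 6 of 9 cases (7 adjusted over the list alone, median 0.50, adjusted p = 0.000835, but adjusted p = 0.367 with an estimated correlation). That basement membrane call ended with the replicate block (0.141), a fit that links these groups only through arrays of prefix I. Immediate-early and heat shock genes fell in 12 of 13 cases (13 adjusted over the list alone, median -1.97, adjusted p = 7.72e-16, and adjusted p = 0.0277 with an estimated correlation), among them Fos (-3.68 ± 0.20) and Hspa1a (-3.35). Unfolded protein response genes fell in 9 of 13 cases (median -0.38, adjusted p = 5e-04, but adjusted p = 0.367 with an estimated correlation), led by the chaperone gene Dnajb9 (-1.23 ± 0.14). Hypoxia genes were 1 higher and 6 lower of 15 (2 and 8 adjusted over the list alone, adjusted p = 0.0855). The trypsinogen gene Prss3 (3.18 ± 0.73, adjusted p = 0.00203) and Reg3b (3.15 ± 0.54, adjusted p = 0.00011) rose beside acinar list means of 10.39 in normal islets, with Normal2007 at 8.26, and 11.39 in islet tumours.

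The remaining list calls between islet tumours and normal islets lay near the threshold and ended under several settings. Pericyte genes rose in 4 of 10 cases (adjusted p = 0.0348, but adjusted p = 0.744 with an estimated correlation), and the call ended without Normal2006 (0.222), islet tumour II-649 (0.0765) or II-6415 (0.0646), without dim genes (0.0688), with array weights (0.0846) and with the lymphocyte covariate (0.0518). Neuroendocrine secretory genes fell in 6 of 15 cases and rose in 1 (8 and 1 adjusted over the list alone, median -0.34, adjusted p = 0.0431, but adjusted p = 0.654 with an estimated correlation). That call ended without NormalI-93 (0.0775) or Normal2007 (0.063), islet tumour I-9811 (0.057) or II-649 (0.0596), with quantile normalization (0.356) or median centring (0.0603), without dim genes (0.0699) and with the acinar covariate (0.0955). Sterol and fatty acid genes fell in 6 of 15 cases and rose in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.0487, but adjusted p = 0.654 with an estimated correlation). It ended without NormalI-93 (0.156) or Normal2007 (0.0505), islet tumour II-649 (0.0767) or II-6415 (0.0671), and with either covariate, quantile normalization or median centring or without dim genes (0.0521 to 0.0768). In all, 5785 genes differed, 2584 higher and 3201 lower (44.7% higher, and 33.9% with median centring), and 11 of 25 lists were called, 5 of them higher, of which 2 held with an estimated correlation. In the 5 comparisons of larger groups, 6 to 49 of the 56 or 100 splits of the same arrays, the real one included, gave as many called lists, so chance was not excluded for their number.

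The name of the metastasis-like class raises the question whether these primaries and the liver metastases differ from islet tumours in the same genes. Of the 2455 genes higher in metastasis-like primaries, 1701 were also higher in liver metastases and 42 were lower there. Of the 2824 lower genes, 2186 were also lower in liver metastases and 27 were higher. Both comparisons use the same islet tumours as control, and the overlap to be expected from that was not computed. Serpina1c, Tfap2b, Peg10, Cartpt and Gpx3 rose in both, and Bace2 and Ucn3 fell in both. Across genes, which are not independent replicates, both sets of fold changes had a correlation of 0.705 and a covariance of 0.161, and 75.2% of genes had the same sign, against a mean of 64% in unchanged groups sharing the islet tumours. For the correlation, unchanged groups sharing the islet tumours gave a mean of 0.415 and a covariance of 0.00798. Over 1000 simulations this correlation ran from 0.0136 to 0.71, a range that leaves out the extremes at both ends and still holds the observed 0.705. With shared islet tumours the correlation alone thus does not tell the groups from unchanged ones. With the islet tumours split between both comparisons the correlation was 0.639 (0.589 to 0.663 over both uses of 10 splits). Unchanged groups gave a mean of -0.000637 (-0.399 to 0.408, again without the extremes), and 67.5% of genes had the same sign, against 50%. If primaries were put in their class by a likeness of expression to metastases, the shared genes and this correlation would follow from that choice. The unchanged groups do not account for such a choice, so the likeness is not an independent result.

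**Figure D4:**
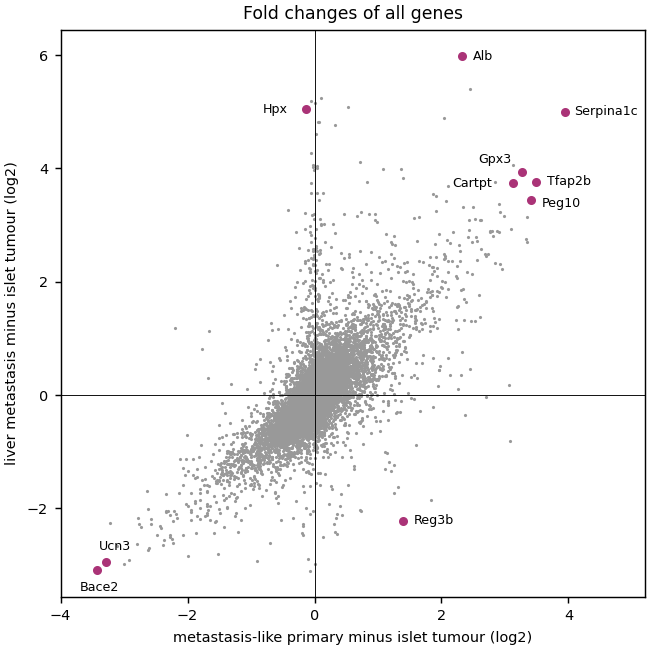
Log2 fold change of each of 19938 genes against islet tumour, metastasis-like primaries on the horizontal and liver metastases on the vertical axis, 1 grey point per gene, with 10 named genes marked. Serpina1c, Tfap2b, Peg10 and Cartpt lie high on both axes, Bace2 and Ucn3 low on both, and Hpx high in liver metastases alone.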

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

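The tests of the 3 patterns weighed here and the splits of the samples were chosen after the results were seen.

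Xist stood between 10.67 and 11.41 log2 in all 9 islet arrays and between 5.33 and 6.46 in the 13 tumour and metastasis arrays. Silencing of Xist in female tumours was argued against for 12 of the 13: female cells lack Y-linked genes, but the mean of Kdm5d, Eif2s3y and Uty lay above all 9 islet arrays in these 12, and the lowest of the 13 lay 2.18 log2 above Normal2006 (5.15). That lowest array, islet tumour III-8017 (7.33), lay below 7 of the 9 islet arrays and at -1.02 log2 from the lowest of the other 12, between these and Normal2006, so a share of female tissue without Xist is open there. Islet samples taken from both sexes, set against tumours of males, remain a candidate explanation. The Y-linked mean was 1.32 log2 higher in the 13 arrays than in the 9 islet arrays (permutation p = 4e-05, two-sided). The permutation treated all arrays as independent, but the islet groups share replicate codes, and samples of the same code resembled each other. The p-value may therefore be too small. The labels give no sex, so a link between sex and tumour stage is open and untested.

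Immediate-early and heat shock genes averaged 9.18 to 9.75 in the islet arrays and 7.31 to 8.15 in the others, a step of 1.40 between the closest group means. The scaling of the arrays was argued against as the whole cause, since the smaller fall under quantile normalization or median centring, from angiogenic islets to islet tumours, was still -1.75. Isolation of islets against dissection of tumours cannot be told apart from tumour stage, because the 3 islet group means lay within 0.262 of each other and every islet group precedes every tumour group. The series text does not say which tissue was handled in which way.

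Liver tissue in the liver metastases is consistent with 18 of 18 hepatocyte genes being higher there than in metastasis-like primaries. In angiogenic islets such tissue may also have been present: with the hyperplastic islet level subtracted from both, 14 hepatocyte genes stood at a median of 9.28% of the metastases, beside 22.9% for Alb (15 of 18 measured genes were used, without Ambp, Fga and Tat, which rose by less than 2 log2 from islet tumours to metastases). Angiogenic2006 (8.83%) and Angiogenic2007 (19%) carry this median but AngiogenicI-93 (-0.504%) does not, and leaving out 1 array gave 4.11% to 13.9%. In metastasis-like primaries, with the islet tumour level subtracted, the same genes stood at a median of 0.961% beside 11.7% for Alb. Liver tissue was argued against as the whole source of Alb in III-8016 (0.144% beside 40.3%) and III-8023 (0.373% and 7.97%). Alb also exceeded the other genes in Angiogenic2006 (8.83% beside 27.8%), but by a smaller factor. Without III-8016 the values were 1.19% and 4.49%. Traces of liver tissue are open in I-9812 (1.39% and 7.88%), II-648 (0.665% and 1.65%) and II-6413 (0.558% and 0.466%), and expression of these genes by tumour cells was not tested.

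Of 68 values tested over both groups of 5, 8 had a sample far from the others, and chance gives about 1 in 20. In metastasis-like primary III-8016 the hypoxia list mean was 8.68 log2 (8.25 to 8.35 in the others), the acinar mean 9.88 (11.54 to 12.12), Cpa1 11.76 (12.96 to 13.12) and Xist 6.28 (5.33 to 5.46). Pecam1 stood at 8.32 in metastasis-like primary II-6413 (7.70 to 7.87). In islet tumours, the red blood cell mean was 7.04 in I-9811 (6.43 to 6.51), the interferon mean 8.51 in III-8024 (7.18 to 7.36) and Krt19 7.31 in III-8017 (6.33 to 6.55).

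Other splits of the same arrays were compared with the real one by the number of called genes. In 3 comparisons 1 of 56 splits, the real one, gave as many genes. These were islet tumours against angiogenic islets (1903, highest other 471), islet tumours against normal islets (5785 and 1470) and liver metastases against metastasis-like primaries (3126 and 1699). That argues against chance only if the arrays are independent samples, and the labels do not say which samples came from separate animals. For metastasis-like primaries against islet tumours it was also 1, of 100 splits drawn from 126 (5279 and 779), and for liver metastases against islet tumours 1 of 56 (7296 and 1739). If primaries were put in their class by expression, the real split gives more genes there by construction, so chance is not excluded in these comparisons. The splits treat arrays as exchangeable, but all 3 liver metastases share prefix I, which 1 islet tumour and 1 metastasis-like primary carry. In both comparisons with metastases a difference between prefixes, or the metastases' smaller spread within 1 prefix, may therefore add to the counts. With the replicate block the counts were 2892 and 6371 genes, but that fit links metastases and primaries only through arrays of prefix I. For 3 against 3 arrays the 10 splits are too few for a share below 0.05: hyperplastic islets gave 1722 genes (highest other 0, 1 split as large) and angiogenic islets 505 (highest other 313, 1 split as large). Of the 4 splits that part all 3 pairs of the same code, the others gave 0 genes in both comparisons, and the 313 came from a split that parts fewer pairs.

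For the number of called lists chance cannot be excluded. Counting the real split, as many lists were called in 6 of 56 splits for islet tumours against angiogenic islets (13, highest other 15), in 49 of 100 for metastasis-like primaries against islet tumours (7 and 11) and in 36 of 56 for liver metastases against these primaries (7 and 13). The same held in 9 of 56 for liver metastases against islet tumours (10 and 12) and in 9 of 56 for islet tumours against normal islets (11 and 13). With 10 splits too few for a share below 0.05, hyperplastic islets had 5 called lists (highest other 9, 9 splits as large) and angiogenic islets 10 (highest other 12, 4 splits as large).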

How the results depend on the processing

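The acinar and lymphocyte covariates were chosen after the result was seen. Counts are given in the order of the 7 comparisons of the report. Counts of called genes stayed within 1.5 times the reported ones with quantile normalization, median centring, the filter on dim genes, all probe sets and a trended robust variance. With the replicate block they were 2112, 616, 2696, 5738, 2892, 6371 and 4470, and called lists 7, 11, 16, 6, 5, 10 and 13. In the first 2 comparisons, which the codes pair, the block changed no list call other than those the report gives. Islet tumours and metastasis-like primaries of the same prefix had correlations of -0.087 to 0.206 across genes, against -0.278 to 0.167 for other prefixes, so prefixes did not clearly pair them. The nearest title numbers within a prefix gave -0.035 (II-6415 and II-6413) to 0.206 (I-9811 and I-9812). No fit that pairs them was run, so a pairing of single tumours is open. In the other 5 comparisons the block ended the calls of neuronal genes in metastasis-like primaries against islet tumours (adjusted p = 0.0516), and of fibroblast (0.0506) and interferon genes (0.19) in liver metastases against these primaries. It also ended those of basement membrane genes in liver metastases against islet tumours (0.278) and of basement membrane (0.141), pericyte (0.564) and neuroendocrine genes (0.189) in islet tumours against normal islets. In these 5 comparisons it added 9 list calls, among them cell cycle genes, which turned lower in islet tumours against angiogenic islets (0.000114). Apart from metastasis-like primaries against islet tumours, the block links the groups of these comparisons only through arrays of prefix I. The calls that it ended or added there are therefore no check on the full groups. With a change of at least 2-fold they were 343, 114, 243, 745, 454, 1204 and 905, fewer by construction. For hyperplastic against normal islets the lymphocyte covariate gave 1118 genes, and for angiogenic against hyperplastic islets array weights gave 930. For islet tumours against angiogenic islets a fit of the compared arrays gave 768 and the lymphocyte covariate 321. For liver metastases against metastasis-like primaries array weights gave 5377 and the acinar covariate 1910. Leaving out 1 array gave 1162 to 1608, 275 to 869, 732 to 2228, 4845 to 5183, 1950 to 3415, 5962 to 7293 and 4583 to 5905 genes. The count was 275 without Hyperplastic2006, 316 without Hyperplastic2007, 284 without Angiogenic2006 and 869 without Angiogenic2007. In the next comparison it was 732 without AngiogenicI-93 and 1025 without Angiogenic2006, and later 1950 without liver metastasis I-9821 and 1988 without I-9822. An estimated correlation left 1, 5, 3, 0, 1, 0 and 2 called lists. Hyperplastic against normal islets had 9 lists in a fit of the compared arrays, 2 with fry and 6 to 8 without 1 array (8 without Hyperplastic2006), and liver metastases against metastasis-like primaries had 4 with fry. Other list counts without 1 array were 9 to 12, 13 to 15, 6 to 9, 7 to 8, 9 to 11 and 9 to 12. The concordance across genes was 0.639 with the islet tumours split and 0.668 to 0.725 without 1 array. Except for the 2-fold minimum, the cause was not tested. Of 519 named gene results 0 reversed, and calls ended for 69 with the block, 57 and 47 with the lymphocyte and acinar covariates (including members of the lists from which these covariates were made), 54 in a fit of the compared arrays, 15 with quantile normalization, 10 each with array weights and a trended robust variance, and 5 with median centring. Leaving out 1 array ended the call in 340 of 4178 such results. Signal over background was not analysed here.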

Other observations

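No test was added for these values, and their genes were chosen after the result was seen. Genes of organised lymphoid tissue differed between islet samples of the same group. The B-cell gene Ms4a1 stood at 9.19 log2 in AngiogenicI-93, 8.998 in Angiogenic2006 and 5.10 in Angiogenic2007, and at 8.63, 7.69 and 6.22 in the hyperplastic islets of the same codes. The complement receptor gene Cr2, found on B cells and follicular dendritic cells, stood at 8.36, 8.39 and 5.52 in the same 3 angiogenic islets. The B-cell attractant Cxcl13 stood at 10.08, 9.01 and 6.25 in the angiogenic islets and at 9.71, 9.18 and 6.45 in the hyperplastic islets. In the 5 islet tumours Ms4a1 stood between 4.96 and 5.34, Cr2 between 5.11 and 5.57 and Cxcl13 between 5.87 and 7.24, highest in III-8024. In the 3 normal islets Cxcl13 stood between 7.72 and 8.09 while Ms4a1 stood between 5.47 and 5.88, so Cxcl13 did not follow Ms4a1 there.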
